A study of Arabidopsis thaliana with 8 samples.

How the data were processed

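Total RNA from dissected vegetative apices with their leaf primordia was measured on Affymetrix ATH1 arrays, 1 array per sample, in 4 genotypes of Arabidopsis thaliana with 2 arrays each. The deposited values are on a log2 scale, and per the submitters' processing notes the tools named are GCRMA, which corrects the background, normalises between arrays and summarises probes, and limma. Versions, array scan dates and a genome build were not given in the sources used here. The scale was checked on the values, which ran from 2.12, a floor shared by all 8 arrays, to 15.55, with array medians of 5.9 to 5.97. The Col-0 columns carry more decimals than the other 6, and nothing in the labels says why. If the Col-0 arrays were processed apart from the others, every contrast with Col-0 and the interaction would include that difference.

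The 22810 probe sets include 64 Affymetrix controls, which stayed out of the tests. In the platform annotation used here 13513 probe sets had exactly 1 gene, 503 had several and 8730 had none listed. Of the single-gene probe sets, 13436 matched the gene table of assembly TAIR10.1 by Entrez identifier. A probe set without a single listed gene is given by its identifier. None of the 12 GRF and GIF genes had a named probe set. The levels of GIF1 and GRF3, which would check the genotype labels, could therefore not be assigned to a probe set. The tested probe sets without a listed gene may include them.

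Probe sets with a log2 value of at least 4 on at least 2 of the 8 arrays were tested, which left 14005, of which 7599 had exactly 1 gene. The contrasts, tests, alternatives, naming rule and a first set of 28 gene lists were fixed before the data were examined. Group means were fitted to all 8 arrays with limma 3.58.1 (lmFit, contrasts.fit and eBayes, no trend, not robust) in R 4.3.3, and 6 contrasts were taken: each transgenic genotype against Col-0, the double line against each single line, and the interaction, which is the double line minus rGRF3 minus the difference between 35S:GIF1 and Col-0. P-values were adjusted by the Benjamini-Hochberg method within each contrast and called at 0.05. Tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

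The sample labels carry the letters A and B and do not say whether these were separate cultures or what the letter marks. P-values therefore measure only the spread between these samples, which may be technical, and the number of arrays limits the precision. Whether the letters pair the arrays was checked before the fits were compared, by the correlation across probe sets of the A minus B deviations between genotypes. All 6 pairs of genotypes had a correlation between 0.59 and 0.75, and each of the 8 arrays correlated best with an array of its own letter, so the letters were taken to pair the arrays. This pairing comes from the data and not from the labels, and with 2 letters it rests on pairs of genotypes. Results come from the planned fit without the letter, and values with the letter as a replicate block are printed where they change a call or a count. The planned fit ignores this pairing and counts the difference between the letters as spread. A probe set that did not pass in it is therefore not shown to be unchanged.

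Gene lists were tested with limma's camera (preset correlation 0.01, two-sided) over 1 probe set per gene, the one with the highest mean signal, with adjustment over 108 tests (18 lists by 6 contrasts). Of the 28 first lists, 2 had 5 or more tested members (G2/M cell cycle, and cell expansion and wall loosening), because the annotation names 70 of their 474 members. A further 19 lists were written after the annotation was seen and before any fold change was computed, and 16 of these could be tested. The ribosomal protein and mitotic lists were entered by locus identifier from general knowledge, without a table of their members to check them against. The tubulin, serine carboxypeptidase-like and UDP-glycosyltransferase lists were taken by gene symbol, and the plastid-encoded list by chromosome. Camera was also run with an estimated correlation, and fry was run for both its directional and its mixed p. With an estimated correlation the adjustment gave many tests the same adjusted p of 0.805. Their unadjusted p-values differed, such as 0.0416 for tubulins in 35S:GIF1 and 0.412 for ribosomal proteins in rGRF3, each against Col-0. That value therefore does not rank the lists, and a list that did not pass there is not shown to be unchanged.

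Genes were named by this rule: per contrast with Col-0 the 10 largest changes per direction, and per other contrast 5, among single-gene probe sets that passed with both arrays beyond both arrays of the other group (not required for the interaction). No single-gene probe set passed, so the rule gave the 5 lowest p-values per direction. For a list it gave up to 4 passing members per direction, or otherwise the 2 members with the largest change. The text names part of the genes so chosen.

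Both tests were tested on simulated data, 10 sets of 8 arrays with 14005 probe sets, of which 200 were changed in the double line against Col-0. A separate list of probe sets was raised there by a smaller amount and left out of the counts below. Camera called that list in 10 of 10 sets and an unshifted list in 0, at an unadjusted p under 0.05. The members of these lists varied independently, unlike those of real lists. At an adjusted p of 0.05 the fit without a block recovered 10.3% of 2-fold, 67.2% of 4-fold and 85.6% of 8-fold changes. The fit with the block recovered 55.1%, 93% and 98.8% of them. Calls of unchanged probe sets averaged 0.1 per simulated set without the block and 9.5 with it. An adjusted p of 0.05 allows a share of all calls to be false, so the 9.5 go with the larger number of changed probe sets recovered. These sets gave every genotype the same spread, which the Col-0 arrays exceeded. Alternatives covered the filter, normalisation, variance model, array weights, samples in the fit, block, floor, thresholds, the list tests and leaving out each array.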

Results

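Transcript levels in vegetative apices with leaf primordia were compared between wild-type Arabidopsis (Col-0), 35S:GIF1, rGRF3 and the combination rGRF3x35S:GIF1, here called the double line. GIF1 is a transcriptional co-activator that binds GRF transcription factors, and the 35S promoter drives strong expression in most tissues. In published work rGRF3 denotes a GRF3 version that microRNA miR396 does not cleave. Apices came from plants grown on soil for 20 days in 8 h light and 16 h dark at 23 °C. Each genotype had 2 arrays, lettered A and B, and between 60.2% and 60.7% of probe sets had a log2 signal of at least 4 on each array.

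DFR, UF3GT, AT5MAT and HYH were among the genes that differed most between the arrays lettered A and B. DFR, which encodes dihydroflavonol reductase of anthocyanin synthesis, had a log2 signal of 5.66 ± 0.86 on the A arrays and 10.45 ± 0.55 on the B arrays (SD, n = 4 each), a 27.8-fold difference (adjusted p = 0.00038). UF3GT, a flavonoid glycosyltransferase gene, was 27.1-fold higher on the B arrays, and the anthocyanin acyltransferase gene AT5MAT was 17.5-fold higher. Both had means under a log2 signal of 4 on the A arrays (3.21 and 2.34, with the arrays' floor at 2.12), so the size of these differences is not exact. The fixed anthocyanin and flavonoid list had 2 of its 12 members tested and was not tested as a list. HYH, a bZIP factor of light signalling, was 17.5-fold lower on the B arrays (adjusted p = 0.00262), where 2 of its 4 values lay under a log2 signal of 4, so this size is not exact either. Plastid-encoded transcripts were also lower there, with a median log2 difference of -0.67 over 66 genes, none of which was higher (adjusted p = 1.09e-17 by camera, adjusted p = 0.572 with an estimated correlation). The control probe set for 25S ribosomal RNA had a mean of 8.31 on the A arrays and 6.69 on the B arrays, and was lower on the B array in 3 of the 4 genotypes. In all, 1658 probe sets were higher and 1781 lower on the B arrays in limma's fit with genotype. Of these 3439, 3428 differed in the same direction in all 4 genotypes, which their selection on the same arrays makes likely. This comparison of letters, and the genes named in it, were chosen after the data were seen.

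**Figure D1:**
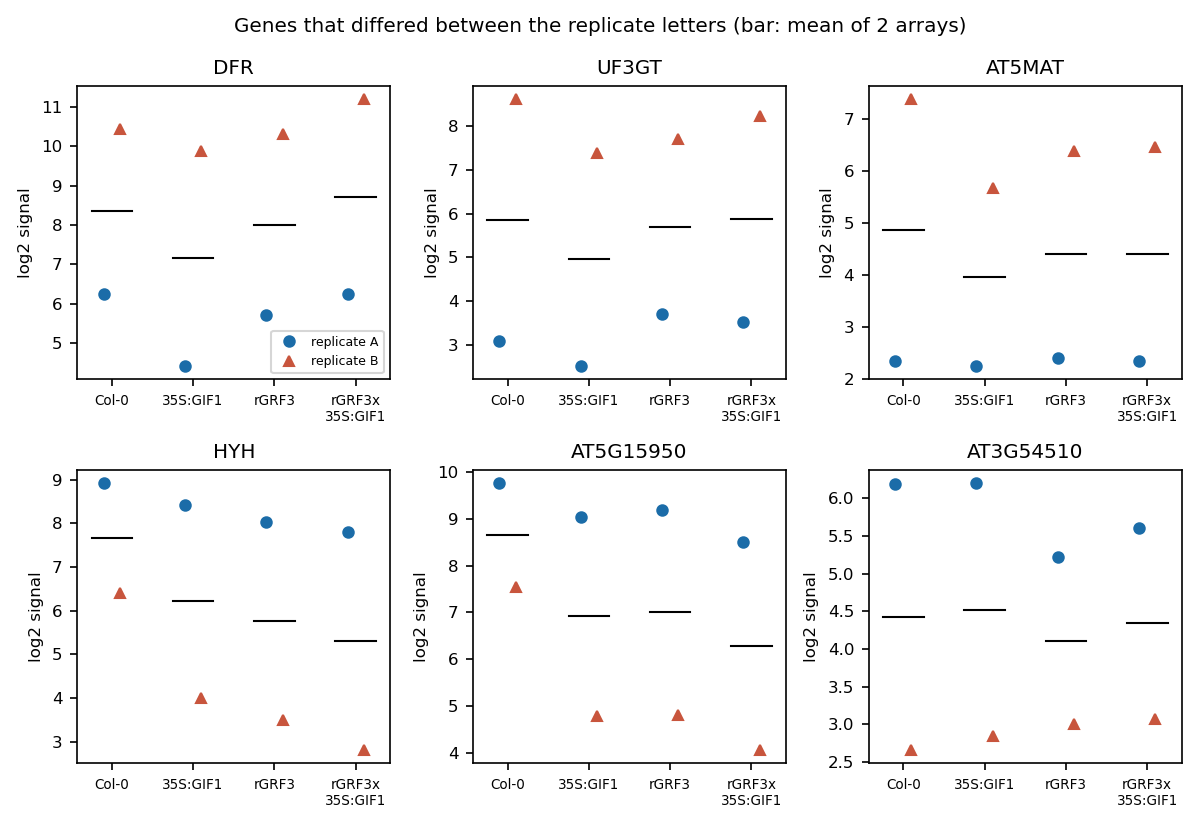
Log2 signal of 6 genes on each of the 8 arrays, by genotype, with circles for replicate A, triangles for replicate B and bars for the mean of 2 arrays. DFR averaged 5.66 on the A arrays and 10.45 on the B arrays, and HYH averaged 8.3 and 4.18.

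35S:GIF1 was compared with Col-0 to find transcripts that differ when GIF1 is driven by the 35S promoter. One probe set, 246103_at, for which the annotation lists no gene, rose from a log2 signal of 9.18 ± 0.06 in Col-0 to 15.06 ± 0.31 in 35S:GIF1 (SD, n = 2 each), a 58.7-fold increase (log2 fold change 5.88, standard error 0.27, adjusted p = 0.00742). It was also high in the double line (13.58) and not in rGRF3 (8.86), so its signal followed the 35S:GIF1 transgene. Whether it measures GIF1 itself cannot be told from this annotation. The level in 35S:GIF1 lies near the highest signal on these arrays (15.51), so the size of the increase is not exact. In all, 198 probe sets had an unadjusted p under 0.05, and 714 with the block, against 917 in simulated unchanged groups with each genotype's own spread. The fit without the block takes the difference between the letters as spread, so the 700 expected by chance do not apply to its counts. Of the single-gene probe sets, none passed. Those with the lowest p-values included STZ (AT1G27730), a zinc-finger repressor of stress responses, which was 6.09 ± 0.50 in Col-0 and 2.90 ± 0.52 in 35S:GIF1 (SD, n = 2 each, log2 fold change -3.19, adjusted p = 0.462). The second value lies near the floor of 2.12, so the size of the difference is not exact. They also included AT4G20830 (log2 fold change 1.01), AT5G01210 (1.25), AT4G27280 (-1.60) and IAGLU (-1.35), which encodes an auxin glucosyltransferase. Among gene lists, tubulins were higher in 35S:GIF1, with 6 of 7 members above Col-0, a median log2 fold change of 0.23, and medians of 0.17 within letter A and 0.28 within letter B (adjusted p = 0.004 by camera, adjusted p = 0.805 with an estimated correlation). TUB5 (0.62) and TUB1 (0.46) had the largest log2 fold changes and did not pass over all probe sets, and adjusted over the list alone 0 tubulins passed, or 2 with the replicate block. Camera also called the serine carboxypeptidase-like list higher, with 10 of 14 members above Col-0 and a median of 0.04 (adjusted p = 0.0142 by camera, adjusted p = 0.805 with an estimated correlation). The median was 0.10 within letter A and 0.01 within letter B, where 7 of 14 members were higher. Its members scpl31 (1.35) and SCPL34 (0.55) had the largest log2 fold changes. Over the list alone 0 members passed, or 2 with the block. Plastid-encoded genes had a median of -0.09 (adjusted p = 0.43) and passed with the replicate block (adjusted p = 0.0405, and adjusted p = 0.844 with the block and an estimated correlation), but their median was 0.06 within letter A and -0.31 within letter B. The 7 G2/M cell cycle genes (median 0.12, adjusted p = 0.216 by camera) and the 6 cell expansion and wall loosening genes (median 0.27, adjusted p = 0.0892) did not pass, and each list had 0 members past the threshold, also when adjusted over the list alone. With the replicate block 246103_at passed at adjusted p = 0.000672, and its log2 fold change was 6.14 within letter A and 5.61 within letter B. Without the block its call ended when any 1 of the Col-0 or 35S:GIF1 arrays was left out, while its log2 fold change stayed between 5.66 and 6.1. The call also ended without a filter (adjusted p = 0.171 in limma's fit), in an ordinary linear model (0.584) and with the arrays of the 2 groups alone (0.206). The tubulin call ended without Col-0 replicate A or 35S:GIF1 replicate B. The carboxypeptidase call ended without Col-0 replicate A, 35S:GIF1 replicate B or rGRF3x35S:GIF1 replicate B, or without a filter (adjusted p = 0.143 by camera). Fits without 1 array leave a genotype with a single letter, and tubulins had a median difference of 0.40 between the letters. These fits therefore cannot separate dependence on 1 array from the difference between the letters.

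**Figure D2:**
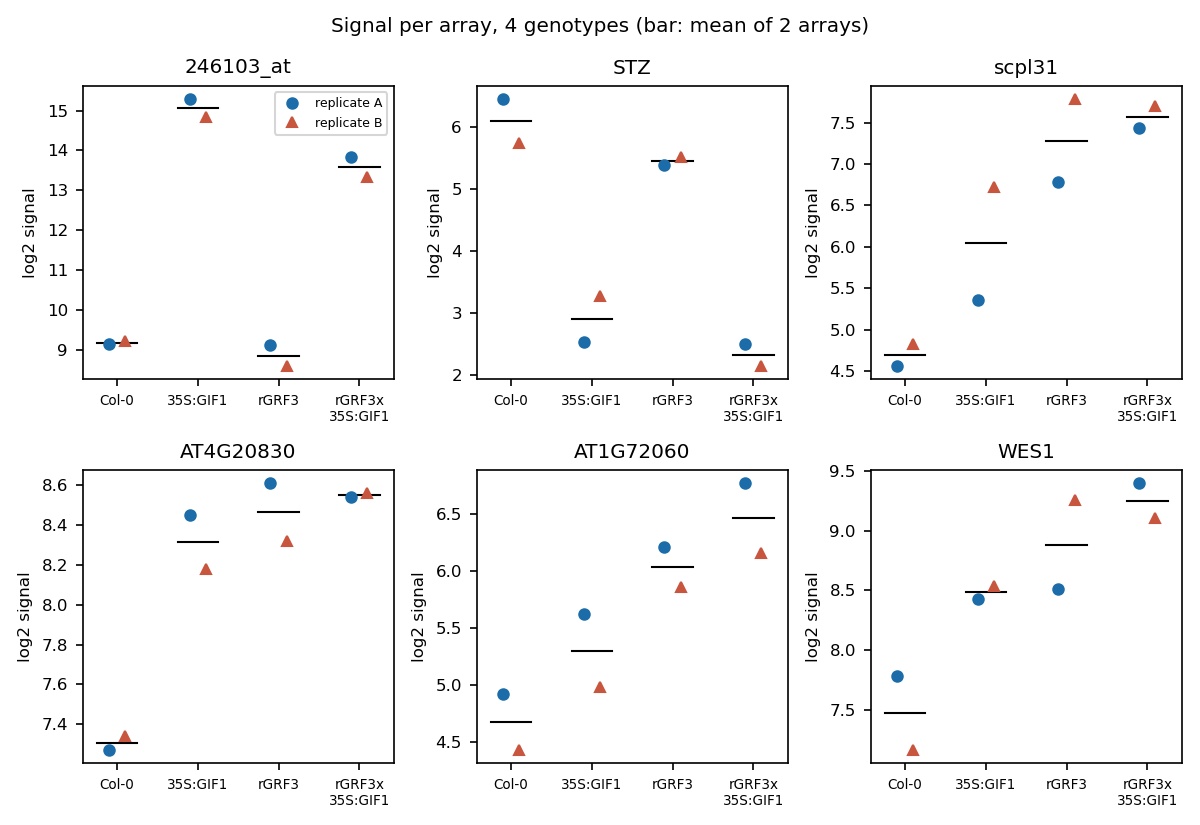
Log2 signal of 246103_at and 5 genes on each of the 8 arrays, by genotype, with circles for replicate A, triangles for replicate B and bars for the mean of 2 arrays. Probe set 246103_at lay between 8.6 and 9.23 in Col-0 and rGRF3 and between 13.33 and 15.28 in the lines carrying 35S:GIF1.

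rGRF3 was compared with Col-0 to find transcripts that differ when GRF3 is free of the microRNA. No probe set passed in limma's fit (0 of 14005, with 479 at an unadjusted p under 0.05), nor with the replicate block (0, with 1581 at an unadjusted p under 0.05, against 1266 in simulated unchanged groups with each genotype's own spread) or an ordinary linear model (0). Without a filter 1 passed, and with the block and a trended, robust variance model, chosen after the data were seen, 13 did. The lowest p-value belonged to 263914_at, for which the annotation lists no single gene and which was named after its values were seen. It was 7.75 ± 0.21 in Col-0, 7.88 ± 0.31 in 35S:GIF1, 9.77 ± 0.11 in rGRF3 and 9.63 ± 0.04 in the double line (SD, n = 2 each, log2 fold change 2.03, adjusted p = 0.418 in limma's fit and 0.139 with the replicate block). Its signal was thus higher in both lines carrying rGRF3, and whether it measures GRF3 itself cannot be told from this annotation. Among single-gene probe sets, those with the lowest p-values included AT4G20830 (log2 fold change 1.16), scpl31 (AT1G11080, 2.59), AT5G01210 (1.41), AT1G28600 (-1.77) and AT4G12830 (-1.21), none of which passed. The scpl31 gene encodes a serine carboxypeptidase-like protein, and its log2 signal was 4.69 ± 0.19 in Col-0 and 7.28 ± 0.70 in rGRF3 (SD, n = 2 each). Its list was higher in rGRF3, with 10 of 14 members above Col-0 and a median of 0.13 (0.21 within letter A and 0.02 within letter B, adjusted p = 0.0107 by camera, adjusted p = 0.805 with an estimated correlation), and 1 member passed over the list alone, or 2 with the block. Genes for cytosolic ribosomal proteins were lower, with 95 of 110 below Col-0 and a median of -0.10 (adjusted p = 0.000243 by camera, adjusted p = 0.805 with an estimated correlation). Within letter A their median was 0.00 and within letter B it was -0.17. The carboxypeptidase call ended without Col-0 replicate A, rGRF3 replicate A or rGRF3x35S:GIF1 replicate B, or without a filter (adjusted p = 0.145 by camera). The ribosomal protein call ended without Col-0 replicate B or rGRF3 replicate B. Fits without 1 array leave a genotype with a single letter, so part of such a change may be the difference between the letters.

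The double line was compared with Col-0 to find transcripts that differ when both transgenes are present. Probe set 246103_at rose to 13.58 ± 0.36 (SD, n = 2), 21.1-fold above Col-0 (log2 fold change 4.40, standard error 0.27, adjusted p = 0.0422), and it was the only one of 14005 to pass, with 902 at an unadjusted p under 0.05. With the replicate block 5 probe sets rose and 0 fell, with 2450 at an unadjusted p under 0.05, against 1169 in simulated unchanged groups with each genotype's own spread. These were 246103_at, the unnamed 264902_at (log2 fold change 2.15) and 262793_at (1.75), AT1G72060 (1.79, blocked adjusted p = 0.0297) and ATSBT5.2 (1.46, blocked adjusted p = 0.0442), a subtilisin-like protease gene. The last 4 were named after their values were seen, and 264902_at had a Col-0 mean of 3.79, under a log2 signal of 4, so the size of its difference is not exact. STZ was 2.32 ± 0.25 in the double line (SD, n = 2), a log2 fold change of -3.77 that did not pass (adjusted p = 0.117, and 0.0514 with the block) and whose size is not exact so near the floor of 2.12. AT2G22890 (1.06), AT4G20830 (1.25), AT4G12830 (-1.42), AT1G28600 (-1.75) and AT4G27280 (-2.16) also had low p-values and did not pass.

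Plastid-encoded genes were lower in the double line than in Col-0 as a list, with 62 of 66 below Col-0 and a median log2 fold change of -0.54 (adjusted p = 2.93e-08 by camera, adjusted p = 0.805 with an estimated correlation). Their median was -0.33 within letter A and -0.58 within letter B. The photosystem II genes psbB (-1.96) and psbT (-1.80) had the largest log2 fold changes and did not pass over all probe sets. Adjusted over the list alone 0 plastid-encoded genes passed, and with the replicate block 35 of the 66 fell. Ribosomal protein genes were lower, with 98 of 110 below Col-0 and a median of -0.17 (adjusted p = 1.09e-08 by camera, adjusted p = 0.805 with an estimated correlation), but the median was -0.02 within letter A and -0.32 within letter B. The carboxypeptidase-like list was higher, with 13 of 14 above Col-0 and a median of 0.29 (0.29 within letter A and 0.30 within letter B, adjusted p = 0.000143 by camera, adjusted p = 0.805 with an estimated correlation). Its members scpl31 (2.87) and SCPL34 (0.87) did not pass over all probe sets, and 1 member passed over the list alone, or 2 with the block. Over their lists alone, with and without the block, the beta-glucosidase gene BGLU33 fell (-0.98) and the trichome birefringence-like gene TBL38 rose (0.97), and neither list passed. With the block alone 2 tubulins, 2 UDP-glycosyltransferase genes and 1 gene of the expansin and xyloglucan endotransglucosylase list rose. The 7 G2/M genes (median -0.01) and 6 cell expansion genes (median 0.10) did not pass, with 0 members past the threshold adjusted over the list alone (1 cell expansion gene with the replicate block). A control probe set for 25S ribosomal RNA stood at 10.9 on the A array and 6.34 on the B array of the double line, against 6.22 and 7.01 in Col-0. On the A and B arrays it stood at 7.88 and 6.66 in 35S:GIF1 and at 8.23 and 6.76 in rGRF3. With the replicate block 246103_at passed at adjusted p = 0.0038. Without the block its call ended when any 1 of the 8 arrays was left out, while its log2 fold change stayed between 4.15 and 4.65, and was 4.69 within letter A and 4.1 within letter B. It also ended without a filter (0.162), with array weights (0.101), in an ordinary linear model (0.279) and with the arrays of the 2 groups alone (0.74). Without rGRF3x35S:GIF1 replicate B the plastid median was -0.13, the ribosomal protein median -0.06 and the carboxypeptidase median 0.19. Without Col-0 replicate A the plastid median was -0.29 and the carboxypeptidase median 0.21. These calls ended in these fits. They set 1 letter of a line against both letters of the other, and plastid genes had a median difference of -0.67 between the letters. The plastid values therefore cannot separate dependence on 1 array from the difference between the letters.

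**Figure D3:**
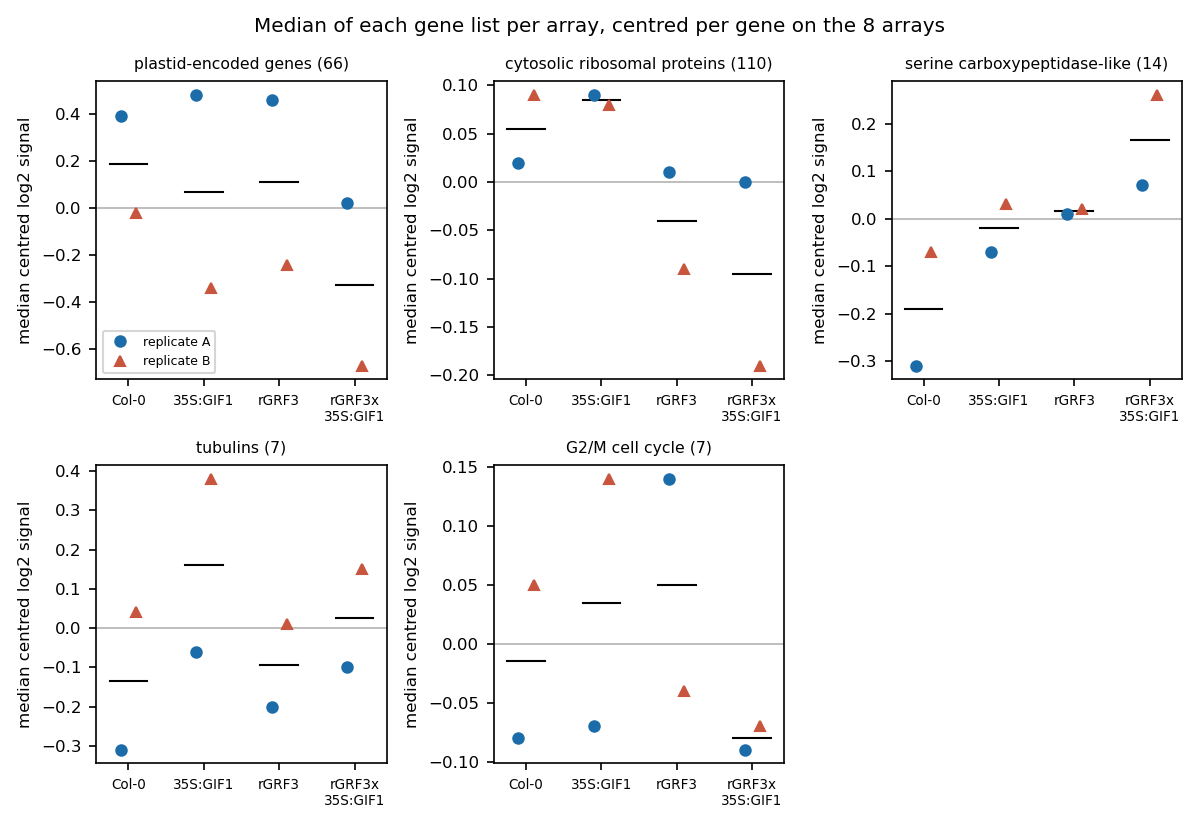
Median log2 signal of 5 gene lists on each of the 8 arrays, centred per gene on its mean over the arrays, by genotype, with circles for replicate A, triangles for replicate B, bars for the mean of 2 arrays and the number of genes in each title. Plastid-encoded genes were at 0.02 and -0.67 on the A and B arrays of the double line and at 0.39 and -0.02 on those of Col-0.

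The double line was compared with rGRF3 to find transcripts that differ when 35S:GIF1 is added. Probe set 246103_at rose 26.4-fold (log2 fold change 4.72, standard error 0.27, adjusted p = 0.0276), and no other passed. STZ had a log2 fold change of -3.13, again not exact near the floor, and did not pass (adjusted p = 0.438). PDF1.2b, a plant defensin gene (-3.77), GID1C, a gibberellin receptor gene (-0.93), AT5G04670 (1.01) and AT5G62150 (1.2) did not pass either. AT5G62150 had a mean of 3.68 in rGRF3 and PDF1.2b one of 3.91 in the double line, both under a log2 signal of 4, so these sizes are not exact. PDF1.2b had log2 fold changes of -4.93 within letter A and -2.62 within letter B. Plastid-encoded genes were lower, with 61 of 66 below rGRF3 and a median of -0.51 (-0.43 within letter A and -0.40 within letter B, adjusted p = 1.28e-14 by camera, adjusted p = 0.805 with an estimated correlation), and 0 of them passed over the list alone, or 19 with the block. With the block 1 AGAMOUS-like gene also fell over its list alone. Ribosomal protein genes had a median of -0.05 (adjusted p = 0.000133 by camera) and carboxypeptidase-like genes one of 0.15 (adjusted p = 0.0258), both with adjusted p = 0.805 with an estimated correlation. Within letter A these medians were -0.01 and -0.02, and within letter B they were -0.11 and 0.25. With the replicate block 246103_at passed at adjusted p = 0.00249. Without the block its call ended when any 1 array was left out, while its log2 fold change stayed between 4.46 and 4.99, and was 4.71 within letter A and 4.73 within letter B. It also ended without a filter (0.156), in an ordinary linear model (0.462) and with the arrays of the 2 groups alone (0.691). Without rGRF3x35S:GIF1 replicate B the medians of the plastid, ribosomal protein and carboxypeptidase lists were -0.07, 0.02 and 0.05, and without rGRF3 replicate A they were -0.09, -0.02 and 0.14. All of these calls ended in these fits. They set 1 letter of a line against both letters of the other, and plastid genes had a median difference of -0.67 between the letters. The plastid values therefore cannot separate dependence on 1 array from the difference between the letters. The carboxypeptidase call also ended without Col-0 replicate A (adjusted p = 0.058) or rGRF3 replicate B (0.177), or without a filter (0.0537).

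The double line was compared with 35S:GIF1 to find transcripts that differ when rGRF3 is added. No probe set passed (0 of 14005 in limma's fit, with 354 at an unadjusted p under 0.05, 0 with the replicate block, with 1194, and 1 in an ordinary linear model or 2 without a filter). AT1G43590 (log2 fold change 4.33), AT3G61160 (1.05), AT1G79620 (0.74) and AT1G51080 (-0.85) had low p-values without passing. AT1G43590 had a mean of 3.25 ± 1.6 in 35S:GIF1 (SD, n = 2), where 1 array lay at the floor of 2.12, so its value is not exact, and it was 5.73 within letter A and 2.94 within letter B. AT3G61160 (3.43) and AT1G79620 (3.33) also had means under a log2 signal of 4 in 35S:GIF1. Ribosomal protein genes were lower, with 106 of 110 below 35S:GIF1 and a median of -0.20 (-0.09 within letter A and -0.29 within letter B, adjusted p = 3.42e-17 by camera, adjusted p = 0.805 with an estimated correlation). Plastid-encoded genes were lower in 65 of 66, with a median of -0.41 (-0.43 within letter A and -0.30 within letter B, adjusted p = 6.43e-10 by camera, adjusted p = 0.805 with an estimated correlation). Carboxypeptidase-like genes were higher in 13 of 14, with a median of 0.20 (0.11 within letter A and 0.27 within letter B, adjusted p = 0.00442 by camera, adjusted p = 0.805 with an estimated correlation), and 0 passed over the list alone, or 1 with the block. UDP-glycosyltransferase genes had a median of 0.15 (0.10 within letter A and 0.18 within letter B) and passed with the replicate block alone (adjusted p = 0.0345, against 0.118 without it, and adjusted p = 0.742 with the block and an estimated correlation). Without rGRF3x35S:GIF1 replicate B the plastid median was -0.06 and the carboxypeptidase median 0.08, and without 35S:GIF1 replicate A they were -0.04 and 0.18. Both calls ended in these fits. They set 1 letter of a line against both letters of the other, and the plastid list had a median difference of -0.67 between the letters. The plastid values therefore cannot separate dependence on 1 array from the difference between the letters.

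The interaction asked whether the effect of 35S:GIF1 differed between the rGRF3 and Col-0 backgrounds. No probe set passed (0 of 14005 in limma's fit, with 123 at an unadjusted p under 0.05, 0 with the block, with 480, and 0 in an ordinary linear model). AT5G04670 (1.3), AT5G01740 (1.31), GID1C (-1.18) and AT4G20830 (-0.92) had low p-values without passing. All 7 G2/M genes lay below 0 with a median of -0.29 (-0.34 within letter A and -0.13 within letter B, adjusted p = 0.00675 by camera, adjusted p = 0.805 with an estimated correlation), and 0 members passed, also when adjusted over the list alone. The spindle checkpoint gene BUBR1 (-0.35) and AT4G14330 (-0.38) had the largest values. The overlapping list of mitotic kinesin, condensin, Aurora kinase and checkpoint genes had 14 of 16 members below 0 and a median of -0.15 (-0.30 within letter A and -0.06 within letter B, adjusted p = 0.00584 by camera, adjusted p = 0.805 with an estimated correlation). Plastid-encoded genes had a median of -0.35 (-0.51 within letter A and -0.12 within letter B, adjusted p = 5.1e-07 by camera) and ribosomal protein genes one of -0.07 (-0.06 within letter A and -0.10 within letter B, adjusted p = 0.00014), both with adjusted p = 0.805 with an estimated correlation. Tubulins had a median of -0.15 (-0.12 within letter A and -0.09 within letter B) and passed with the replicate block alone (adjusted p = 0.0306, against 0.124 without it, and adjusted p = 0.742 with the block and an estimated correlation). Fits without 1 array leave a genotype with a single letter, so their medians also carry the difference between the letters, which was -0.67 for plastid genes. They cannot separate that difference from dependence on 1 array. The G2/M, mitotic, plastid and ribosomal protein calls all ended without rGRF3 replicate A (medians -0.20, -0.10, 0.01 and -0.05) or rGRF3x35S:GIF1 replicate B (-0.33, -0.19, -0.01 and 0.03). Without Col-0 replicate A the G2/M (-0.17), mitotic (-0.11) and ribosomal protein (-0.04) calls ended, without 35S:GIF1 replicate B the G2/M (-0.13) and mitotic (-0.11) calls, without rGRF3x35S:GIF1 replicate A the G2/M call (-0.23), without Col-0 replicate B (-0.11) or 35S:GIF1 replicate A (0.05) the plastid call, and after quantile normalisation the ribosomal protein call (-0.05, adjusted p = 0.127).

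The log2 fold changes of the 3 lines against Col-0 were correlated across probe sets, which are not independent replicates. The correlation was 0.77 between rGRF3 and the double line, 0.68 between 35S:GIF1 and the double line, and 0.60 between the single lines. Within letter A these correlations were 0.60, 0.63 and 0.60, and within letter B they were 0.82, 0.70 and 0.70. In 100 simulations of unchanged groups that share the Col-0 arrays and have equal spread, each correlation was 0.50. The Col-0 arrays differed more from each other than those of the other genotypes did. The variance of a group mean from differences shared with no other genotype was 0.0486 in Col-0, 0.011 in 35S:GIF1, 0.0274 in rGRF3 and 0.0227 in the double line. In simulations with these spreads, chosen after the data were seen, unchanged groups gave correlations of 0.66, 0.75 and 0.72. The covariances were 0.0948, 0.0646 and 0.0501, against 0.0498, 0.0497 and 0.0498 in these simulations and 0.0281, 0.028 and 0.0282 with equal spread. One probe set, 246103_at, was called in both 35S:GIF1 and the double line. With the replicate block and at an unadjusted p under 0.05, rGRF3 and the double line shared 509 probe sets higher in both and 524 lower in both. Unchanged groups with these spreads shared 262 and 261, and independent lists would share 63 and 76. The simulations drew each probe set independently, while real probe sets move together, so they do not give the spread of such counts. 35S:GIF1 and the double line shared 238 higher and 229 lower (253 and 253 in unchanged groups, 27 and 36 if independent). The single lines shared 210 higher and 224 lower (251 and 252 in unchanged groups, 17 and 24 if independent). The 2 Col-0 arrays cannot be split into parts of 2, so part of any excess may come from the shared controls. Fold changes taken in different letters share no array. Between rGRF3 in one letter and the double line in the other their correlations were 0.18 and 0.25. Between 35S:GIF1 and the double line they were 0.12 and 0.16, and between the single lines 0.05 and -0.07. The same line's fold changes in letters A and B correlated at 0.08 for 35S:GIF1, 0.13 for rGRF3 and 0.35 for the double line.

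**Figure D4:**
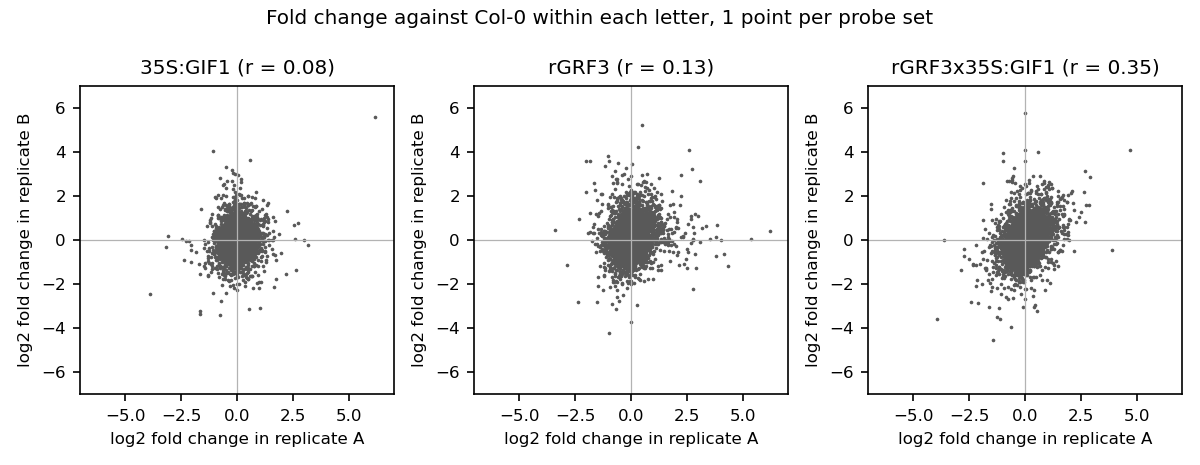
Log2 fold change against Col-0 in replicate A (horizontal axis) and in replicate B (vertical axis) for each of 14005 probe sets, 1 panel per line. The correlation across probe sets was 0.08 in 35S:GIF1, 0.13 in rGRF3 and 0.35 in rGRF3x35S:GIF1.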

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

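The tests of nuclear photosynthesis genes, of the slope along the difference between the letters and of matched random lists were set before their results were seen, and the other tests in this part only afterwards. The effect of 35S:GIF1 differed between the rGRF3 and Col-0 backgrounds for 4 gene lists in camera's test of the interaction. The medians were -0.29 for G2/M cell cycle genes, -0.15 for mitotic kinesin, condensin, Aurora kinase and checkpoint genes, -0.35 for plastid-encoded genes and -0.07 for ribosomal protein genes, and none of the 4 passed with an estimated correlation (adjusted p = 0.805). In data outside the comparisons, the control probe set for 25S ribosomal RNA stood at 10.9 on rGRF3x35S:GIF1 replicate A, above both Col-0 arrays (6.22 and 7.01), and at 6.34 on replicate B. The A arrays of 35S:GIF1 (7.88) and rGRF3 (8.23) also lay above both Col-0 arrays, and their B arrays stood at 6.66 and 6.76.

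The arrays lettered B differed from those lettered A in every genotype. The hybridisation controls had a mean B minus A difference of -0.23 on the log2 scale, while 630 called probe sets differed at least 2-fold. They cannot decide on array brightness, because the deposited values were normalised between arrays before the controls were read. More degraded RNA under one letter is not decided by the 3' minus 5' differences of actin, GAPDH and ubiquitin, which went both ways (-0.12 to 0.18, mean 0.01). That of actin was higher on the B array in every genotype (mean 0.18), while the means for GAPDH (-0.12) and ubiquitin (-0.03) were lower. A growth or harvest day shared within each letter stays open as a candidate explanation, since the lowest correlation of A minus B deviations between genotypes was 0.59, but the labels tie no letter to a day, and anything else the arrays of a letter share would give the same value. No biological explanation was tested, because the letter is not a group of the design.

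Plastid-encoded genes were lower in the double line than in Col-0 within both letters. Less green tissue is not decided by 4 nuclear photosynthesis genes, the only ones of 34 listed with a named probe set. Their median log2 fold change was 0.14 (-0.06 within letter A and 0.34 within letter B, SD over genes 0.39), a result set beforehand as arguing against it. They went both ways, with RCA at -0.2, LHCB4.1 at 0.11, LHCB4.2 at 0.18 and PORB at 0.73. RCA, LHCB4.1 and LHCB4.2 had mean log2 signals of 14.36, 14.15 and 14.01. These lie near the top of the arrays' range, where compression of strong signals could hide a modest fall. A position of the double line further along the difference between the letters is argued against by the slope of 0.099 over 3388 other probe sets (0.17 within letter A and 0.02 within letter B). More RNA without poly(A) tails labelled in Col-0 cannot be excluded, since the 25S ribosomal RNA probe set differed by 4.68 within letter A and by -0.66 within letter B (mean 2.01). An effect of the genotype stays open and untested.

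Ribosomal protein genes were lower in the double line than in Col-0. Compression of strong signals cannot be excluded. The medians of 10000 random lists matched on mean expression were centred on -0.07 and ran from -0.13 to -0.02, so that the list's median of -0.17 lay at percentile 0. That percentile had been set as excluding it, but random lists lack the correlation of 0.41 among the list's genes, with which the list did not pass (adjusted p = 0.805). The pattern may rest on the array of rGRF3x35S:GIF1 replicate B alone, since without it the median was -0.06. Comparisons without that array went different ways. The median was -0.17 for rGRF3 against Col-0 within letter B and -0.09 for the double line against 35S:GIF1 within letter A. Against Col-0 within letter A it was 0 for rGRF3 and -0.02 for the double line. An effect of the genotype stays open.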

How the results depend on the processing

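Alternatives that combine the replicate block with another choice, correlations across letters and simulations with each genotype's own spread were chosen after seeing the data, and the others before. The planned GIF1 and GRF3 fold changes have no values, because no probe set is named for either gene. With the replicate block the double line against Col-0 had 5 calls instead of 1, and the counts of calls for the other contrasts did not change. Probe sets at an unadjusted p under 0.05 went from between 123 and 902 per contrast to between 480 and 2450. The block added 3 list calls by camera, given with their contrasts. In fry's mixed test it gave 7 calls instead of 0, for tubulins and carboxypeptidase-like genes in each line against Col-0 and TON1 recruiting motif proteins in the double line against rGRF3 (adjusted p from 0.00913 to 0.0475). With the block and the trended, robust variance model there were 61 calls for the double line and 13 for rGRF3, and with the block at an adjusted p of 0.10 there were 75 for the double line. Without a block, an adjusted p of 0.10 gave 2 calls for the double line, and 0.01 gave 0 there and against rGRF3. Without a filter there were 0 calls for 35S:GIF1, 1 for rGRF3, 0 for the double line, 3 for it against rGRF3 and 2 against 35S:GIF1. Array weights gave 0 for the double line. The ordinary linear model gave 0 for 35S:GIF1 and 1 for the double line against 35S:GIF1. Fits of 2 groups alone gave 0 calls for 35S:GIF1, for the double line and for it against rGRF3, with 2 residual degrees of freedom. Leaving out each array gave 0 to 1 calls for 35S:GIF1 and 0 for the other contrasts; a group left with 1 array was assumed to vary like the others. Of 108 list tests 17 passed, 0 passed with an estimated correlation, 0 in either form of fry without the block and 0 in directional fry with it, and leaving out each array gave 3 to 20. Without 1 array the letters no longer balance, and 4 list medians changed sign. Over the arrays left out, the ribosomal protein median ran from -0.15 to 0.02 for the double line against rGRF3 and from -0.18 to 0.03 in the interaction, both above 0 without rGRF3x35S:GIF1 replicate B. The plastid median in the interaction ran from -0.71 to 0.05, and was above 0 without 35S:GIF1 replicate A (0.05) or rGRF3 replicate A (0.01). Without a filter the carboxypeptidase calls for 35S:GIF1, rGRF3 and the double line against rGRF3 ended (adjusted p = 0.143, 0.145 and 0.0537). The correlation of fold changes ran from 0.34 to 0.84 over arrays left out for the single lines, from 0.40 to 0.86 for 35S:GIF1 with the double line and from 0.51 to 0.89 for rGRF3 with the double line. Across letters it was 0.05 and -0.07, 0.12 and 0.16, and 0.18 and 0.25. The cause was not tested for any of these except where the alternative tests fewer arrays or other probe sets. Of the counts of calls and the correlations, 161 values stayed within their limits, 63 moved beyond them and 1 changed sign. Of the values of single genes and lists, 1737 kept their direction and side of the threshold, 126 lost the threshold, 30 gained it and 4 changed sign. Signal near the floor of 2.12 limits dim genes such as STZ in 35S:GIF1 and in the double line.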

Other observations

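The comparison of the letters was chosen after its values were seen, and so were the genes of small lists given here. Lists with under 5 tested members had no test as a list. WES1 (AT4G27260), a GH3 gene for conjugating auxin to amino acids, had log2 fold changes of 1.02 in 35S:GIF1, 1.41 in rGRF3 and 1.79 in the double line against Col-0, in that order with adjusted p = 1, 1 and 0.525 in limma's fit. With the replicate block its adjusted p was 0.82, 0.307 and 0.123 in the same order. FMA, a regulator of guard cell formation, had a log2 fold change of -0.67 in the double line (adjusted p = 0.714), and PYK10, a root beta-glucosidase gene, had 0.61 in rGRF3 and 0.71 in the double line (adjusted p = 1 and 0.714). AT1G43590 had a mean log2 signal of 7.66 in rGRF3 and 7.58 in the double line, against 4.69 in Col-0 and 3.25 in 35S:GIF1, where 1 of its arrays lay at the floor of 2.12.

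Further genes separated the letters. AT5G61290 was 15.1-fold, AT1G56300 14.8-fold and AT4G34950 14.7-fold higher on the B arrays, and AT5G15950 was 14.2-fold, AT3G54510 7.5-fold and AT2G41250 6.67-fold lower there. AT5G61290 (3.61) and AT1G56300 (3.11) on the A arrays and AT3G54510 (2.89) on the B arrays had mean log2 signals under 4, so these folds are not exact. HYH differed between the letters by log2 values from -5.01 to -2.52 over the 4 genotypes.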
